A study of Mus musculus with 4 samples.

How the data were processed

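RNA-seq was done on osteoclast precursors, defined in the labels by surface CD11b, c-fms (the M-CSF receptor) and high Ly6C, which were flow-sorted from the spleens of C57BL/6 wild-type mice. There were 2 libraries from control mice (Ctrl 1 and Ctrl 2) and 2 from mice infected with Porphyromonas gingivalis (Pg 1 and Pg 2), a Gram-negative oral bacterium tied to periodontitis. Per the labels' protocols, total RNA was extracted with a column kit that also keeps small RNA and was sent to a company for its standard library construction. The labels do not say whether a library came from 1 mouse or a pool, so p-values measure the spread between these libraries, which may be partly technical.

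The deposited values were normalized read counts, handled here as a signal that the authors had scaled by library, for 16375 Ensembl genes. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and DESeq2 was used, without a version. The aligner, the counting program, its treatment of strand and multi-mapping reads, and the annotation are not given in the sources used here. In each library every deposited value was a whole multiple of a single step, so whole reads could be recovered for 100% of values within a tolerance of 0.001. The step was 0.982 in Ctrl 1, 1.04 in Ctrl 2, 0.950 in Pg 1 and 1.01 in Pg 2. Recovered totals were 15057201 reads in Ctrl 1, 14450892 in Ctrl 2, 11946560 in Pg 1 and 13340127 in Pg 2. The lowest total over the 4 libraries was 41 reads and 0 genes had 40 or fewer, so a gene that is not listed may still be expressed at a low level. A count of 3 reads corresponds to a value of 2.85 to 3.13, depending on the library, and such floors cover counting error only.

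Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which held 16341 of the 16375 identifiers, and from a table of gene names, with a symbol for 16331. Exonic length and GC content were available for 99.7% of the genes. The main test was limma (version 3.58.1 in R 4.3.3) with an intensity trend in the variance, on log2(value + 1), two-sided, over the 15858 genes with a value of at least 10 in at least 2 libraries. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen. Errors of log2 fold changes are standard errors (SE) from limma, and values are given per library or as mean ± SD with n = 2 per group. The residual degrees of freedom were 2 and the prior added 4.29.

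There were 29 gene lists fixed before the data were examined, on osteoclast biology, interferon and bacterial responses, monocyte subsets, other blood lineages and metabolism. Of these, 27 were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 27. The list of sort markers had 4 members, under the minimum of 5, and the sex-linked list served as a check of labels only. Each list was also tested with a correlation estimated from the data, and with fry. With 2 libraries per group the estimated correlation left 0 of the 27 lists with an adjusted p below 0.05, and 4 with an unadjusted p below 0.05. Its lowest adjusted p was 0.301, so no list call holds with an estimated correlation.

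Named genes were taken by a rule fixed before the data were examined. It takes the 4 sort markers Itgam, Csf1r, Ly6c1 and Ly6c2. It also takes the 12 largest rises and the 12 largest falls among genes that passed the test, had a mean value of at least 50, did not overlap between groups and were not predicted gene models. From each list it takes up to 4 members with the smallest p. Genes outside the rule are marked as chosen after their values were seen.

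The procedure was tested on simulated counts drawn for the same 15858 genes and 4 libraries. Changed genes were drawn only from those with a mean of at least 50 reads. Genes were simulated independently, each with a dispersion shared by both groups. The figures that follow therefore do not cover lower genes, correlated genes or a wider spread within Pg. For the comparison of Pg with Ctrl it recovered 43% of 100 genes changed 2-fold and 86% of 100 genes changed 4-fold, and 8.33% of 156 calls fell on unchanged genes. In the same simulation a raised set of 30 genes had a camera adjusted p of 1.51e-40, or 0.0121 with an estimated correlation, and an unchanged set had 0.691.

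Alternatives covered the low-value filter, the pseudocount, TMM and quantile normalization, the variance trend, a replicate block, leaving out each library, stricter and looser thresholds, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A correction for gene length and GC content and a crossed replicate block were added after seeing the data. Shared replicate numbers were not taken to pair libraries, because the labels tie them to no mouse, litter or day. The labels name no sequencing batch. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.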

Results

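Transcriptomes of flow-sorted splenic osteoclast precursors, myeloid cells positive for CD11b and c-fms with high Ly6C, were measured by RNA-seq in 2 control libraries and 2 libraries from mice infected with Porphyromonas gingivalis. The series title speaks of chronic infection and of how osteoclast precursors are characterised and regulated after it. The comparison of Pg with Ctrl asks how expression in this sorted population differs between infected and control mice. Depth was 15057201 and 14450892 reads over the listed genes in Ctrl 1 and Ctrl 2, and 11946560 and 13340127 in Pg 1 and Pg 2. The Ctrl libraries were closer to each other (r = 0.987 across genes on the log2 scale) than the Pg libraries (r = 0.947), where genes are not independent replicates. The first principal component held 65.2% of the variance and separated Ctrl from Pg, and the second held 28.3% and separated Pg 1 from Pg 2.

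Expression of 970 genes rose and that of 621 fell in Pg, of 15858 tested (limma, adjusted p below 0.05, n = 2 per group). The 12 largest rises included 8 genes of neutrophil granules, neutrophil surface or the calprotectin pair, and the largest falls included interferon-induced genes and genes of patrolling monocytes and dendritic cells. The groups did not overlap for 9920 genes (62.6%), where an unrelated ordering of the libraries gives 33.3% on average. Genes vary together, so setting these shares side by side is not a test of infection. Without Ctrl 1 and without Ctrl 2 the rises numbered 372 and 444 and the falls 51 and 68, and without Pg 1 and without Pg 2 the rises numbered 3404 and 4280 and the falls 3479 and 4662. Removing a Ctrl library leaves the spread to the wider Pg pair, and removing a Pg library leaves it to the tight Ctrl pair, with the lone library assumed to vary alike. Without the variance trend 387 rose and 37 fell, and with the added length and GC correction 545 and 391. Quantile normalization changed the split of higher to lower calls from 61% higher to 52.1% higher.

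**Figure D1:**
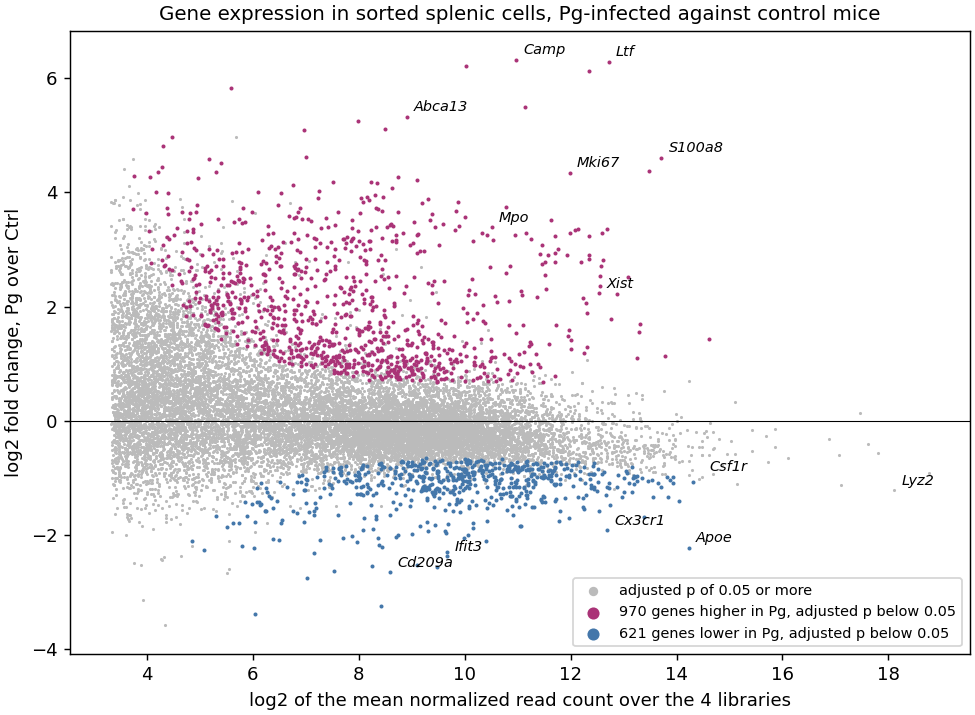
Log2 fold change of Pg over Ctrl against the log2 of the mean normalized read count, 1 point per tested gene. The 970 genes that rose are purple, the 621 that fell are blue, and the labelled genes are discussed in the text except Lyz2.

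Of the genes behind the sort markers, Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491, GRCm38), fell from 3135 ± 303 to 1860.1 ± 219 (log2 fold change −0.75 ± 0.18 SE, limma adjusted p = 0.0485). Its call was lost without Ctrl 1 (adjusted p = 0.574), without Ctrl 2 (0.386), with a pseudocount of 10 (0.0511), without the variance trend (0.129) and with the length and GC correction (0.0853). Csf1r, which encodes c-fms, stood at 30787 and 29286 in Ctrl and 12251 and 18878 in Pg (log2 fold change −0.98 ± 0.28 SE, limma adjusted p = 0.0796; edgeR adjusted p = 0.0624; DESeq2 adjusted p = 4.47e-04). Csf1r was also called lower without Pg 1 (2.84e-07), without Pg 2 (9.37e-19) and with the filter of at least 50 (0.0448). Ly6c2 had 19791 and 18608 in Ctrl and 9909 and 15334 in Pg (limma adjusted p = 0.172; called lower without Pg 1, 0.0145, and without Pg 2, 8.33e-13), and Ly6c1 stayed near 34.4 in Ctrl with 34.2 and 12.2 in Pg (limma adjusted p = 0.427; called lower without Pg 1, 0.00404). Reads of the near-identical Ly6c1 and Ly6c2 cannot be separated with certainty.

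Genes of the cell cycle rose together. Of 40 measured members of the proliferation list, 38 rose, 0 fell, and 39 rose when adjusted over the list alone; the median log2 fold change was 3.09 (camera adjusted p = 8.31e-36, higher). Adjusted p = 0.540 with an estimated correlation. Mki67, a marker of cycling cells (chromosome 7, Ensembl ENSMUSG00000031004), read 316 and 429 in Ctrl and 6038 and 9392 in Pg, a log2 fold change of 4.35 ± 0.27 SE (limma adjusted p = 0.00179). Top2a, the mitotic topoisomerase, rose from 501 ± 5.23 to 5798 ± 1355, Cenpe, a kinetochore motor, from 40.8 ± 7.59 to 811 ± 215, and Nusap1, a spindle protein, from 83.8 ± 3.64 to 830 ± 136. Prr11, among the 12 largest rises and outside the list, went from 7.86 and 9.38 to 175 and 319. The median of the list was 2.86 in Pg 1 and 3.38 in Pg 2 relative to Ctrl.

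Genes of neutrophil granules were tested in 2 parts. Of 10 primary granule genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with a median log2 fold change of 2.74 (camera adjusted p = 1.04e-05; adjusted p = 0.301 with an estimated correlation). Mpo, myeloperoxidase, read 253 and 252 in Ctrl and 2626 and 2687 in Pg (log2 fold change 3.39 ± 0.15 SE, limma adjusted p = 0.00179). Elane, neutrophil elastase, rose by 3.26, Ctsg, cathepsin G, by 2.94 and Ms4a3, a gene of granulocyte-monocyte progenitors, by 3.90 on the log2 scale. The member that fell was Clec12a, an inhibitory lectin receptor, named after its values were seen. The primary granule median was alike in Pg 1 (2.79) and Pg 2 (2.82).

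Of 17 genes of later granules and the neutrophil surface, 9 rose and 0 fell (12 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 2.69 (camera adjusted p = 4.62e-05; adjusted p = 0.614 with an estimated correlation). Camp, the cathelicidin precursor (chromosome 9, 109847379 to 109849617), read 28.5 and 45.8 in Ctrl and 6554 and 1360.4 in Pg, a log2 fold change of 6.33 ± 0.69 SE (limma adjusted p = 0.00481). Ltf, lactoferrin (chromosome 9, 111019271 to 111042767), read 88.4 and 181 in Ctrl and 22268 and 4469 in Pg. Ngp, Lcn2 (a siderophore-binding protein) and Wfdc21 rose by 6.13, 5.51 and 5.12 on the log2 scale. S100a8 and S100a9, the subunits of calprotectin, rose by 4.61 and 4.38, S100a8 reading 763 and 1010 in Ctrl and 40726 and 11337 in Pg. Ly6g, a neutrophil surface marker, read 2.95 and 5.21 in Ctrl, which is close to the floor of 3 reads, and 424 and 66.9 in Pg. The list median was 4.003 in Pg 1 and 1.38 in Pg 2, and 12 rose and 3 fell without Pg 1 and 13 and 4 without Pg 2. Abca13 (21.6 and 22.9 in Ctrl, 970 and 901 in Pg) and Itgb2l (7.86 and 9.38, then 838 and 159) were also among the 12 largest rises.

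**Figure D2:**
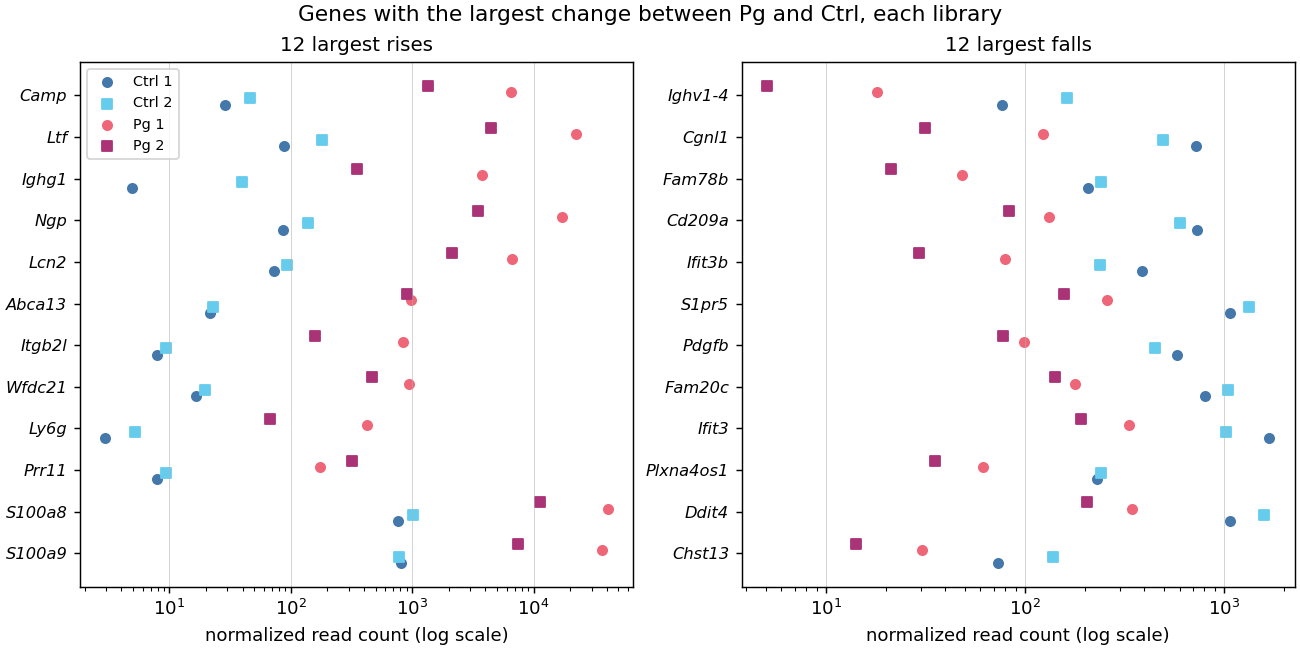
Normalized read counts on a log axis in each of the 4 libraries for the 12 largest rises (left) and the 12 largest falls (right), 1 point per library. Genes whose groups overlap were left out by the naming rule. Late granule genes such as Ltf are higher in Pg 1 (22268) than in Pg 2 (4469).

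Among progenitor, basophil and mast cell genes, 2 of 14 rose and 0 fell (5 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.28 (camera adjusted p = 0.0135; adjusted p = 0.665 with an estimated correlation). Myb, a transcription factor of haematopoietic progenitors, rose from 46.5 ± 0.518 to 276 ± 126 (limma adjusted p = 0.0117). Mcpt8, a basophil protease, read 0.982 and 0 in Ctrl and 150.2 and 41.6 in Pg. Prss34, another basophil protease, read 4.91 and 10.4 in Ctrl and 367 and 35.5 in Pg (limma adjusted p = 0.0704). Flt3, also in the list, went the other way, from 894 and 677 in Ctrl to 445 and 446 in Pg (limma adjusted p = 0.05001). By direction alone 12 of the 14 members were higher and 2 lower. Without Pg 1 the list median was 0.27, camera gave an adjusted p of 0.524 and 5 members rose, and without Pg 2 11 rose. Without Ctrl 2, 3 rose. The call was also lost with the filter of at least 50 (0.290).

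Of 18 genes of non-classical, patrolling monocytes 9 fell and 0 rose (10 fell adjusted over the list alone), with a median log2 fold change of −1.22 (camera adjusted p = 1.19e-05; adjusted p = 0.301 with an estimated correlation). Cx3cr1, the fractalkine receptor, went from 9831 and 10921 to 2519 and 2996 (log2 fold change −1.91 ± 0.19 SE, limma adjusted p = 0.00362). Treml4, Eno3 and Nr4a1, the last a transcription factor required for these monocytes, had log2 fold changes of −1.52, −1.35 and −1.41, and Ear2, whose reads may be shared with close paralogs, of −1.43. Nr4a1 is also a member of the immediate early and dissociation list, which was lower too, so its fall is not particular to these monocytes. S1pr5, a sphingosine-1-phosphate receptor, went from 1209 ± 195 to 208 ± 72.4. By direction alone 14 of the 18 list members were lower and 4 higher. The list median was −1.24 without Ctrl 1, −1.20 without Ctrl 2, −1.11 without Pg 1 and −0.88 without Pg 2. Most calls of members were lost without either Ctrl library and without the variance trend.

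Of 18 classical monocyte genes 1 rose and 2 fell (1 and 4 adjusted over the list alone), with a median log2 fold change of −0.39 (camera adjusted p = 0.0326; adjusted p = 0.700 with an estimated correlation). Vcan, the proteoglycan versican, read 759 and 797 in Ctrl and 3149 and 10859 in Pg, and Ly86 (a partner of a toll-like receptor homologue) and Fcgr1 (the high-affinity IgG receptor) had log2 fold changes of −1.03 and −1.08. The list's call was lost without Ctrl 1 (camera adjusted p = 0.0906), without Ctrl 2 (0.0671) and without Pg 1 (0.608), with quantile normalization (0.963) and with the filter of at least 50 (0.136). Members that fell numbered 0 without either Ctrl library, 9 without Pg 1 and 14 without Pg 2, and those that rose numbered 5 without Pg 1.

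Of 20 tissue macrophage genes 5 fell and 0 rose (5 adjusted over the list alone), with a median log2 fold change of −0.86 (camera adjusted p = 2.42e-04; adjusted p = 0.665 with an estimated correlation). Apoe, apolipoprotein E, went from 27953 and 35415 to 7252 and 6271, and Siglec1, Maf and Axl had log2 fold changes of −1.93, −1.46 and −1.55. The median was −0.19 in Pg 1 and −1.55 in Pg 2. By direction alone 17 of the 20 list members were lower and 3 higher. Fewer members fell without either Ctrl library, and 3 fell with the length and GC correction. In the dendritic cell list 4 of 18 fell and 0 rose (5 fell adjusted over the list alone), among them Batf3 (530 ± 27.2 to 128 ± 8.60) and Cd209a (666 ± 92.9 to 108 ± 34.6), while the list itself was not called (camera adjusted p = 0.0769). Camera called it lower without Pg 1 (8.01e-06), without Ctrl 2 (0.00520) and with the length and GC correction (0.0153). Dendritic cell members that fell numbered 2 without Ctrl 1, 11 without Pg 1 and 6 without Pg 2, when 9 rose and the median was 0.42.

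Of 30 type I interferon response genes 19 fell and 0 rose (25 fell adjusted over the list alone), with a median log2 fold change of −1.07, −1.11 in Pg 1 and −1.03 in Pg 2 (camera adjusted p = 7.81e-13; adjusted p = 0.590 with an estimated correlation). Irf7, a master regulator of interferon induction, went from 6417 and 4460.2 to 1396 and 1811 (log2 fold change −1.75 ± 0.24 SE, limma adjusted p = 0.0110). Bst2 (tetherin) and Cmpk2 had log2 fold changes of −1.52 and −1.04. Ifit3 and Ifit3b had −2.37 and −2.62, and their near-identical sequences leave the split of reads between them uncertain. The members that fell numbered 1 without Ctrl 1, 12 without Ctrl 2, 27 without Pg 1, 28 without Pg 2 and 0 without the variance trend.

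In the interferon gamma and antigen presentation list 10 of 30 fell and 0 rose (19 fell and 1 rose adjusted over the list alone), with a median log2 fold change of −0.82 (camera adjusted p = 1.18e-07; adjusted p = 0.301 with an estimated correlation). Irf1, Gbp2, Igtp and the chemokine gene Cxcl10 had log2 fold changes of −1.38, −1.13, −1.11 and −1.65. By direction alone 26 of the 30 list members were lower and 4 higher. The list median lay between −0.85 and −0.79 when a library was left out. Most calls of members were lost without either Ctrl library. The median was −0.55 with quantile normalization, when 18 fell, and −0.44 with the length and GC correction, when 6 fell, and without the variance trend 0 fell.

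Genes of osteoclast differentiation were lower as a list by camera, while 3 of 28 fell and 0 rose (11 fell adjusted over the list alone), with a median log2 fold change of −0.65 (camera adjusted p = 1.40e-05; adjusted p = 0.590 with an estimated correlation). Those that fell were Jund, an AP-1 subunit (2604 ± 108 to 1119.6 ± 290), Syk, a kinase downstream of immunoreceptors (11011 ± 292 to 5981 ± 522), and Relb, of the alternative NF-kB pathway (855 ± 48.6 to 524 ± 36.4). Nfkb2 read 2425 and 2119 in Ctrl and 1274 and 1502 in Pg (limma adjusted p = 0.0536). Members that fell numbered 0 without Ctrl 1, 0 without Ctrl 2, 18 without Pg 1 and 22 without Pg 2, and 0 after the length and GC correction, when the median was −0.40. Of 14 genes of osteoclast function, 0 passed with limma (2 higher and 3 lower at an unadjusted p below 0.05), 0 with edgeR and 1, lower, with DESeq2. Without Pg 1 3 of them rose and 5 fell, without Pg 2 2 rose and 6 fell, and without either Ctrl library 0 passed. Mmp9, a matrix protease, read 207 and 171 in Ctrl and 2044 and 398 in Pg (limma adjusted p = 0.0885). Its log2 ratio of Pg 1 to Pg 2 was 2.36, near those of the late granule genes Ltf (2.32) and Camp (2.27). Tcirg1 and Itgb3 had log2 fold changes of −0.80 and −0.85. Car2 read 32.4 and 67.7 in Ctrl and 1460 and 100 in Pg. By direction alone 5 of the 14 genes of osteoclast function were higher and 9 lower. The median of the osteoclast function list was −0.19, its mean was 0.13, and camera did not call it (adjusted p = 0.421). The sort-marker genes Csf1r, Itgam, Ly6c2 and Ly6c1 had log2 fold changes of −0.98, −0.75, −0.64 and −0.72, near the median of the differentiation list. Whether that list and the other lower lists fell within cells or through a different mix of sorted cells was not tested.

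Of 25 genes listed as negative regulators of osteoclast formation 6 fell and 0 rose (12 fell and 1 rose adjusted over the list alone), with a median log2 fold change of −0.56 (camera adjusted p = 1.12e-04; adjusted p = 0.301 with an estimated correlation). Cebpa, a myeloid transcription factor, went from 6125 ± 725 to 1902 ± 371 (limma adjusted p = 0.00722), Irf8, a factor of monocyte identity, from 9089 ± 1426 to 4052 ± 462 (limma adjusted p = 0.0230), and Klf2 and Nfkbia had log2 fold changes of −1.36 and −1.30. The list was fixed beforehand, and whether a member, Cebpa included, restrains osteoclast formation in these cells was not tested. By direction alone 19 of the 25 list members were lower and 6 higher. The list median was −0.56 without Ctrl 1 and without Ctrl 2, −0.42 without Pg 1 and −0.74 without Pg 2. Most calls of members were lost without either Ctrl library. After the length and GC correction 3 members fell, and without the variance trend 0 fell.

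Of 30 immediate early and dissociation genes 11 fell and 1 rose (15 and 2 adjusted over the list alone), with a median log2 fold change of −0.67 (camera adjusted p = 1.12e-04; adjusted p = 0.470 with an estimated correlation). Fosb and Hspa1a had log2 fold changes of −2.05 and −2.20, the latter with a near-identical copy, and the member that rose was Hsp90aa1, a heat shock protein, named after its values were seen. By direction alone 23 of the 30 list members were lower and 7 higher. The list median was −0.59 without Ctrl 1, −0.57 without Ctrl 2, −0.72 without Pg 1 and −0.60 without Pg 2. Most calls of members were lost without either Ctrl library, and 1 member fell without the variance trend. With the length and GC correction 5 fell and the median was −0.24 (camera adjusted p = 0.0251). Of 34 bacterial sensing genes 5 fell and 1 rose (8 and 3 adjusted over the list alone), with a median log2 fold change of −0.26 (camera adjusted p = 0.0236; adjusted p = 0.665 with an estimated correlation). Irak2, Clec7a, Cd14 and Nlrp3 fell, by log2 fold changes of −1.20, −1.10, −0.79 and −0.99, and the member that rose was Clec4e, a C-type lectin, named after its values were seen. That list's call was lost without Ctrl 1 and without Pg 1, with quantile normalization (camera adjusted p = 0.110) and with the filter of at least 50 (0.211). By direction alone 23 of its 34 members were lower and 11 higher. The median was −0.23 without Ctrl 1, −0.31 without Ctrl 2, −0.0976 without Pg 1 and −0.47 without Pg 2. Calls of its members were lost without either Ctrl library.

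Several lists were not called by camera in the chosen setting. Of 25 inflammatory and NF-kB target genes 3 fell (8 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.0988), among them Icam1 and Cd40 with log2 fold changes of −1.02 and −1.19. In the anti-inflammatory list 1 of 18 rose (Lcn2) and 1 fell (Tsc22d3, log2 fold change −1.57; 2 and 3 adjusted over the list alone), the median was −0.22, the mean was 0.18 and camera's adjusted p was 0.444. Of 24 genes in the chemokine receptor and adhesion list 2 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.115). Those that rose were Ccr1 and Mmp8, the latter a matrix protease gene, with log2 fold changes of 1.13 and 0.90. Those that fell included Cx3cr1 and S1pr5. In the unfolded protein response list Asns rose (2.65) and Herpud1 fell (−0.81) of 16 (1 and 1 adjusted over the list alone; camera adjusted p = 0.179). Asns read 221 and 57.8 in Pg. Its call was lost with edgeR (adjusted p = 0.0563), TMM and quantile normalization, a pseudocount of 10, the length and GC correction, and without the variance trend. In the glycolysis and hypoxia list Pfkfb4 and Slc16a3 fell (−1.12 and −0.84) of 25 (2 adjusted over the list alone; camera adjusted p = 0.410). Without Pg 1 the falls in these 5 lists numbered 14, 7, 15, 5 and 4, and without Pg 2 9, 7, 11, 10 and 13, in the order given. Without Ctrl 1 they numbered 0, 1, 2, 0 and 0, and without Ctrl 2 0, 0, 2, 0 and 0. The rises numbered 3, 4, 6, 4 and 7 without Pg 1, 6, 4, 8, 1 and 4 without Pg 2, 0, 1, 1, 0 and 0 without Ctrl 1, and 0, 1, 0, 1 and 0 without Ctrl 2. Camera called the inflammatory list lower without Pg 1 (adjusted p = 6.14e-04) and without Ctrl 2 (0.0410), and the chemokine list lower without Pg 1 (0.00154) and with the length and GC correction (0.0468).

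Markers of other lineages differed between Pg 1 and Pg 2: the erythroid median was high in Pg 1 and near Ctrl in Pg 2, where some members were higher, and medians of B and of T and NK genes lay above Ctrl in Pg 1 and below it in Pg 2. Of 15 erythroid genes 0 passed with limma (4 higher at an unadjusted p below 0.05), 0 with edgeR and 4 with DESeq2, and the median was 3.30 in Pg 1 and −0.11 in Pg 2 relative to Ctrl. Camera called the list (adjusted p = 0.00751; adjusted p = 0.675 with an estimated correlation), and the call was lost without Pg 1 (0.815) and with the filter of at least 50 (0.0961). Without Pg 2 15 erythroid genes rose, without Pg 1 3 rose and 2 fell, and without Ctrl 2 2 rose. Klf1, an erythroid transcription factor, read 1.96 and 9.38 in Ctrl and 233 and 19.3 in Pg. Of 20 B and plasma cell genes 0 passed with limma (1 lower at an unadjusted p below 0.05), 0 with edgeR and 1 with DESeq2, and the median was 1.10 in Pg 1 and −1.78 in Pg 2 (camera adjusted p = 0.379). Without Pg 1 20 of them fell and camera called the list lower (2.59e-22), and without Pg 2 18 rose and 1 fell and it was called higher (2.26e-12). Of 20 T and NK cell genes 0 passed with limma, edgeR or DESeq2, and 0 at an unadjusted p below 0.05, and the median was 1.41 in Pg 1 and −1.30 in Pg 2 (camera adjusted p = 0.605). Without Pg 1 15 fell (called lower, 5.93e-05), and without Pg 2 20 rose (called higher, 4.11e-09). Of 10 megakaryocyte and platelet genes 0 passed in any of these ways (camera adjusted p = 0.497), while without Pg 2 5 rose (called higher, 0.0496) and without Pg 1 1 fell. Ighg1, an immunoglobulin constant region gene, was among the 12 largest rises taken by the naming rule, reading 4.91 and 39.6 in Ctrl and 3788 and 348 in Pg (limma adjusted p = 0.0343), although immunoglobulin genes share sequence. There were 110 genes with a value in Pg 1 above 5 times that of every other library, and 0 such genes in each of the other 3 libraries.

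**Figure D3:**
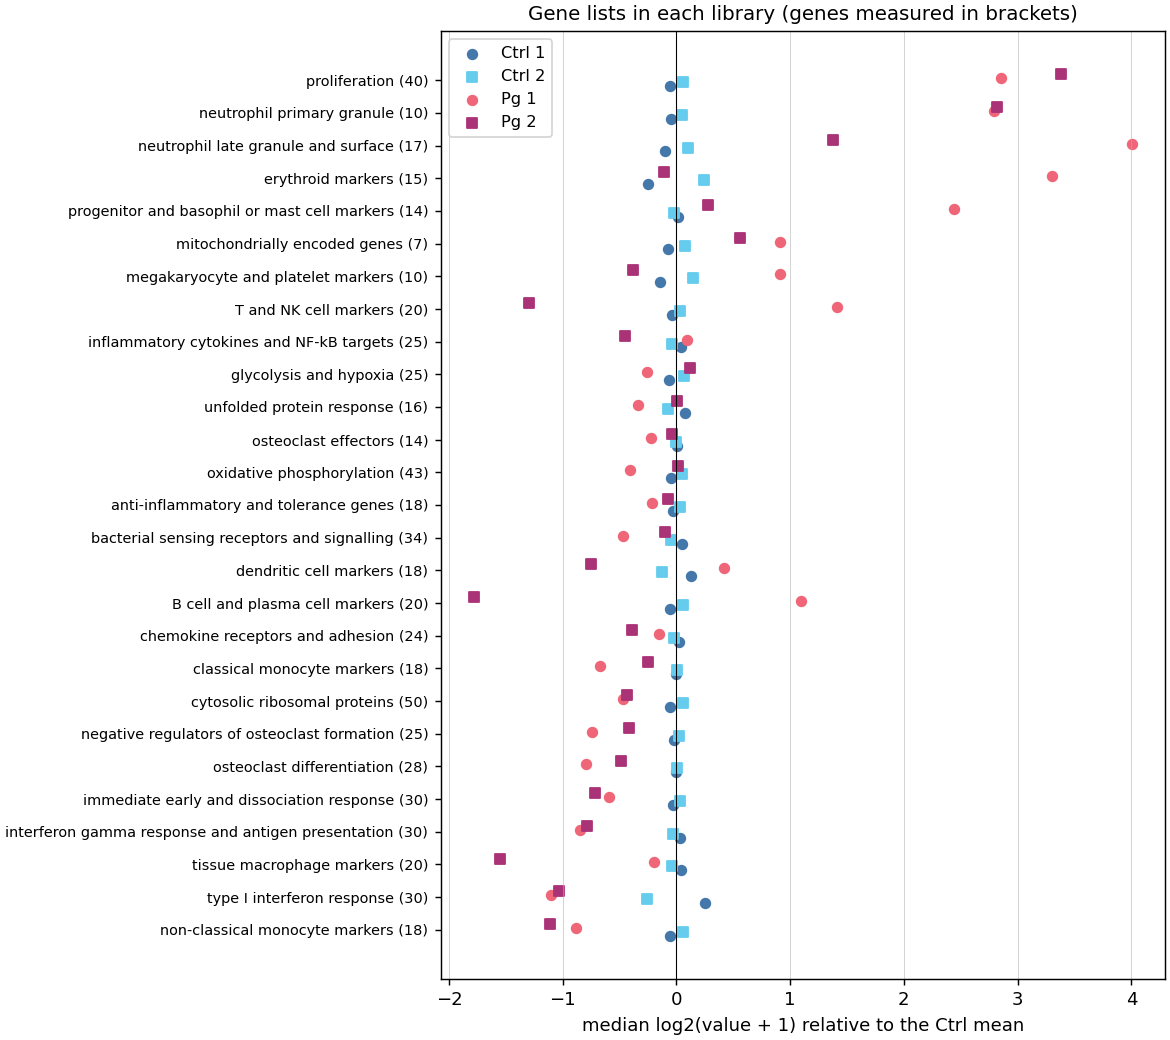
Median over each gene list of log2(value + 1) relative to the mean of the Ctrl libraries, 1 point per library. The proliferation list lies at 2.86 in Pg 1 and 3.38 in Pg 2, while the erythroid list lies at 3.30 in Pg 1 and −0.11 in Pg 2.

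Ribosomal protein genes were lower as a list, with 1 of 50 members falling (0 adjusted over the list alone) and a median log2 fold change of −0.44 (camera adjusted p = 1.06e-08; adjusted p = 0.665 with an estimated correlation), and quantile normalization reduced the median to −0.0756 and ended the call (0.446). After the length and GC correction the median was −0.31 (camera adjusted p = 1.10e-04). Short genes were lower in general. Among protein-coding genes with a mean value of at least 100, the 2256 of shortest exonic length had a median of −0.45 in Pg 1 and −0.20 in Pg 2 relative to Ctrl, against 0.0445 and 0.22 for the 2255 longest. Such a trend can come from RNA or library quality. The member that fell was Rpl24 (3236 ± 145 to 1946 ± 48.6), and 40 fell without Pg 1, 44 without Pg 2 and 0 without either Ctrl library. Oxidative phosphorylation genes had a median of −0.21 over 43 members, of which 0 passed with limma (2 lower at an unadjusted p below 0.05), 0 with edgeR and 0 with DESeq2 (camera adjusted p = 0.00841; adjusted p = 0.762 with an estimated correlation). Without Pg 1 that median was 0.0177, of opposite sign to the test, 5 members rose and 3 fell, and camera's adjusted p was 0.982, and without Ctrl 2 it was 0.0636. The call was also lost with quantile normalization (median −0.0620, 0.625), with the length and GC correction (median −0.0538, 0.115) and with the filter of at least 50 (0.136). Without Pg 2 34 fell. Of 7 mitochondrially encoded genes 3 rose, mt-Nd5, mt-Nd6 and mt-Nd4, all subunits of complex I, by 1.39, 1.06 and 0.97 (4 adjusted over the list alone; camera adjusted p = 0.00516; adjusted p = 0.665 with an estimated correlation), and the list's median turned from 0.73 to −0.16 after the length and GC correction. Without either Ctrl library 0 of the 7 rose, and without either Pg library 5.

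Further large falls lay outside the lists. Ighv1-4, an immunoglobulin variable gene, read 76.6 and 163 in Ctrl and 18.1 and 5.07 in Pg. Cgnl1, a junction protein gene, fell from 610 ± 161 to 77.5 ± 65.1, Pdgfb, a growth factor gene, from 518 ± 93.4 to 88.4 ± 14.7, Fam20c, a secretory-pathway kinase gene, from 930 ± 177 to 160.3 ± 25.99, and Ddit4, a stress-induced inhibitor of mTORC1, from 1340 ± 371 to 276 ± 99.8. Fam78b, Chst13 and Plxna4os1 had log2 fold changes of −2.76, −2.23 and −2.31. Plxna4os1 is annotated antisense, and with strand not given in the sources used here its reads cannot be told from those of its partner. Among the 12 largest falls, calls lost when a library was left out were Chst13 and Ifit3b without Ctrl 1, and Chst13 and Ighv1-4 without Ctrl 2. The 12 largest rises kept their calls without each library in turn. Leaving out a Pg library could not show otherwise, since every call of the main fit was then kept. With edgeR the calls of Ighg1, Cgnl1, Chst13 and Ifit3b were lost, and without the variance trend 4 of the 12 rises and 3 of the 12 falls kept theirs.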

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

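The length and GC correction and the crossed block were chosen after seeing the data. Of 1987 gene values under alternatives, 1648 kept direction and side of the threshold, 182 lost the call, 146 gained it and 11 reversed; of 432 list values, 355 kept both, 48 lost the call, 15 gained it and 14 reversed. None of the 1591 changed genes was called in the opposite direction under an alternative, while among B, T and NK genes 20 and 15 fell without Pg 1 and 18 and 20 rose without Pg 2. Of 66 called list genes followed singly, 27 kept their call without Ctrl 1, 30 without Ctrl 2, 43 with the length and GC correction and 17 without the variance trend. The cause was not tested except where stated.

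Changed genes numbered 1591 (970 higher, 621 lower), and 424 (387 and 37) without the variance trend, 936 (545 and 391) with the length and GC correction and 3145 (1756 and 1389) at an adjusted p below 0.1. Lower genes numbered 1136 with quantile normalization, 1008 with DESeq2 and 351 at an absolute log2 fold change of at least 1. Leaving out a library gave 423 to 8942 changed genes, 372 to 4280 higher and 51 to 4662 lower, which follows from the spread then coming from the other group's pair. edgeR called 2016 genes, sharing 952 higher and 566 lower. The median of all genes was −0.0180, and 0.11 with edgeR, a shift over 0.1. Lists called numbered 17, 0 with an estimated correlation, 19 with fry mixed and 7 with fry one-way. The 7 were proliferation, primary granule, non-classical monocyte, interferon gamma, negative regulators and 2 that camera did not call, osteoclast effectors and chemokine (0.0368 each). The other 12 camera calls were lost with fry one-way, among them type I interferon (0.121), osteoclast differentiation (0.113), late granule (0.130) and immediate early (0.0606).

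The replicate numbers were not taken as pairs (deviation correlation −0.12). The replicate block called 1910 genes (1182 higher and 728 lower) and 18 lists, with dendritic (0.0308) and inflammatory (0.0492) lists added and classical monocyte lost (0.0725), as were Itgam, Relb, Rpl24 and Syk, and 2 osteoclast effectors rose. The crossed pairing called 2165 genes and 17 lists, with dendritic in place of classical monocyte.

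Medians that turned when a library was left out ranged from −1.30 (without Pg 1) to 1.41 for T and NK, −0.11 to 3.30 for erythroid, −0.38 to 0.91 for megakaryocyte, −0.26 to 0.12 for glycolysis, −1.78 to 1.10 (without Pg 2) for B cell, −0.75 to 0.42 for dendritic, −0.46 to 0.0977 for inflammatory, −0.34 to 0.00630 for unfolded protein response and −0.41 to 0.0177 for oxidative phosphorylation. The test's direction alone turned for classical monocyte (without Pg 1, medians −0.67 to −0.25), osteoclast effectors (without Pg 2, medians −0.22 to −0.0355) and megakaryocyte (0.15 without Ctrl 1). The B cell median was 0.40 with edgeR and 0.27 with DESeq2. Single genes ranged from −0.20 to 1.96 for Cd3e, −0.00584 to 1.75 for Nkg7, −0.17 to 0.85 for Pf4, −0.19 to 1.15 for Vwf, −2.06 to 0.73 for Fcmr and −3.53 to 0.89 for Vpreb3. Quantile normalization turned the test's direction for anti-inflammatory (median −0.0422) and the medians of T and NK (−0.0829), megakaryocyte (−0.0214), unfolded protein response (0.0405) and glycolysis (0.19). The signs of the inflammatory, anti-inflammatory, glycolysis, dendritic and T and NK medians also turned under other alternatives, at values within 0.1 of 0. The length and GC correction turned mitochondrially encoded (−0.16), glycolysis (0.21), mt-Nd2 (−0.27), mt-Nd4 (−0.0494) and mt-Nd6 (−0.13), and edgeR turned Fcmr (0.0535) and Vpreb3 (0.0930). With 2 libraries a group and 11946560 to 15057201 reads, changes of 2-fold were missed in most simulated genes.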

Other observations

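All classes of genes and transcripts below, Kcnq1ot1, Rn7sk, and the tests on Pg 1, on granule sources and on introns, were chosen after the results were seen; the tests on the length and GC trend (itself an added correction), the progenitor genes and the glucocorticoid genes were written before their results.

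Replication-dependent histone genes rose with the cell cycle genes: 50 of 54 rose and 0 fell, with a median log2 fold change of 2.66, 2.39 in Pg 1 and 2.86 in Pg 2. Many histone genes share sequence, so values of single copies are uncertain. Of 35 kinesin genes 13 rose and 0 fell, with a median of 1.33 in Pg 1 and 0.26 in Pg 2. Immunoglobulin variable genes differed between the Pg libraries, with a median over 121 genes of 1.79 in Pg 1 and −1.05 in Pg 2 relative to Ctrl, and 0 rose and 2 fell. Xist, the noncoding RNA of the inactive X chromosome, was expressed in all 4 libraries, at 1981 and 2179.6 in Ctrl and 9797 and 9803 in Pg (log2 fold change 2.24 ± 0.17 SE, limma adjusted p = 0.00189), and 0 of 4 Y-linked genes were listed. Kcnq1ot1, an imprinted nuclear antisense RNA, read 209 and 249 in Ctrl and 1269.7 and 927 in Pg.

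The rise of the proliferation genes was weighed against 3 explanations. Cells of other lineages in Pg 1 are argued against as the whole source, since without Pg 1 the median log2 fold change was 3.38. After the length and GC correction the median was 3.05, but that correction could hardly have removed a rise of this size. Among protein-coding genes with a mean value of at least 100, the shortest had medians of −0.45 in Pg 1 and −0.20 in Pg 2. The longest had 0.0445 and 0.22. A length trend that small is argued against as the whole source, and GC content was not weighed apart from length. A larger share of granulocyte-monocyte progenitors in the sorted Pg population is a candidate explanation, although a gate on CD11b and high Ly6C would be meant to leave such cells out: in a second list of 11 such genes, not looked at before, 6 rose and 0 fell, all 11 being detected in Ctrl too, with a median of 1.18 (camera adjusted p = 2.91e-04 over 2 added lists; adjusted p = 0.115 with an estimated correlation). That second list cannot tell such progenitors from neutrophil precursors or from other cycling cells. It holds Cdk6, a cell cycle kinase gene. Its member Cebpe was higher in Pg 1 (372) than in Pg 2 (135), as late granule genes were. Dmkn, Plppr3 and Tfec were higher in Pg 2. In the first progenitor list Flt3 went the other way (log2 fold change −0.80), while 12 of the 14 members were higher. Cycling of the same osteoclast precursors after infection stays open and untested.

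Late granule genes were higher in Pg 1 than in Pg 2, as were erythroid, B, T and NK genes. Cells of those lineages in Pg 1 are argued against as the whole source, since without Pg 1 all 17 late granule genes had a median of 1.38, while the medians of those lists were −0.11, −1.78 and −1.30. These medians rest on Pg 2 alone and hold no spread between Pg libraries. Among the genes that rose, the log2 ratio of Pg 1 to Pg 2 had a median of 2.27 over 9 late and −0.18 over 8 primary granule genes, a difference of 2.44. One added source and several for the 2 granule lists cannot be told apart, since these genes were chosen by their call and the difference lies between 2 single libraries. Neutrophils or their precursors in differing amounts, which a gate on c-fms and Ly6C would be meant to remove, may add to primary granule genes of progenitors. S100a8, at 40726 in Pg 1 and 11337 in Pg 2, is part of the pattern to be explained and gives no separate evidence for this. A response of the sorted osteoclast precursors themselves also stays open, untested.

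Sense-intronic genes and unverified transcript models were higher in both Pg libraries. Of 71 sense-intronic genes 62 were higher and 8 rose, with a median of 1.11 in Pg 1 and 1.15 in Pg 2, and of 647 unverified transcript models 92 rose and 3 fell. Nuclear and noncoding transcripts did not all move this way: Xist and Kcnq1ot1 were higher in Pg, while the share of reads on Rn7sk, a nuclear RNA, was 3.83% and 3.96% in Ctrl and 2.70% and 2.30% in Pg, and of 401 lincRNA genes 14 rose and 9 fell, with a median of 0.40 in Pg 1 and 0.0987 in Pg 2. Other lineages in Pg 1 are argued against by that 1.15 in Pg 2. More unspliced RNA or genomic DNA in both Pg libraries may contribute. Protein-coding genes with a mean value of at least 100 were matched on exonic length and level. The 2997 with the longest introns exceeded the 2997 with the shortest by 0.18 (95% bootstrap interval 0.15 to 0.21) in Pg 1 and 0.14 (0.11 to 0.17) in Pg 2, and by 0.00159 between the Ctrl libraries. The intervals come from resampling genes, so they hold no spread between libraries. Preparation and infection status cannot be separated in 4 libraries, and a change in transcription with infection stays open.

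Tsc22d3 and Ddit4, both glucocorticoid-induced, fell. In a list of 10 other glucocorticoid-induced genes, not looked at before, 4 fell and 1 rose, with a median of −0.39 (camera adjusted p = 0.0823 over 2 added lists), which leaves a lower glucocorticoid response as a hypothesis that these data do not decide.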
